A study of Mus musculus with 8 samples.

How the data were processed

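Pro-B cells were sorted from bone marrow of C57BL/6 mice, per the labels, and cells of 6 mice were pooled for each genotype. RNA was extracted with TRIzol and libraries were made with the TruSeq RNA kit v2, per the labels' protocols. Samples were grouped by the genotype in the labels and by the processing tools named for them. Per the submitters' processing notes, the earlier set of 2 libraries was processed with TopHat 1.4.0 and Cufflinks 1.3.2, and the later set of 6 with TopHat2 2.0.13 and Cufflinks 2.2.1. The sequencer was an Illumina HiSeq instrument, per the series' design text. The genome build and annotation are not given in the sources used here. Of 19738 symbols also found in the RefSeq table of GRCm38, 1.33% start within 10 bp of the GRCm38 position, so the coordinates belong to another build and are printed as deposited.

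The authors deposited 1 Cuffdiff comparison of 26049 loci, in columns headed WT and KO, per the file headers. FPKM, fragments per kilobase of transcript scaled to the number of mapped fragments, is given per the file headers as 1 value per genotype, with the bounds of the authors' confidence interval. The log2 fold change, deleted over control without a pseudocount, and the p-value and q-value are the authors', per the file headers. Those columns name no library. All p-values are whole multiples of 5e-05, as Cuffdiff of the Cufflinks 2 series writes them, so the columns were read as the later set, but whether the earlier set entered is not stated. Recomputing the Benjamini-Hochberg adjustment over the 9422 tested loci gave the authors' q to within 5.21e-07. The table marks 16627 loci as not tested, and the lowest mean FPKM of a tested locus was 3.33.

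Because the table holds 1 pooled value per genotype, no replicate test was run here, and the authors' q under 0.05 was the criterion for a change, as fixed for that case before the data were examined. The separate description of the earlier set, the agreement between the sets and the gene set tests over libraries were planned for values per library and were not run. Fold changes computed here are log2 of (FPKM + 1) ratios, which understate the change of low genes, and lists used genes with a mean FPKM of at least 1. That filter kept 13567 loci, of which 2776 have no gene name, and 10283 have 1 symbol that stands at 1 locus, called single-symbol genes here. The control FPKM summed to 3563450 and the deleted to 3129929, and 6 unnamed loci of at most 93 bp held 58.0% of the control sum.

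The 26 gene lists were fixed before the data were examined. Of their entries, 595 matched a symbol, 11 matched by an older symbol, 21 fell on several loci or a shared locus, and 9 were not matched. For each list the median log2 fold was placed among 10000 random lists of the same size, drawn from single-symbol genes in the same 20 bins of mean expression. Percentiles under 2.5 or over 97.5 were called outside. Calls adjusted over the list alone used the Benjamini-Hochberg adjustment of the authors' p-values of the list's tested members. For the heavy chain variable part, the lists were drawn from 2661 unnamed loci outside the immunoglobulin regions. On simulated shifts of the 10283 single-symbol genes, deleted over control, 100 lists per setting were placed likewise, but among fewer random lists. The folds were redrawn independently within the bins, so members that are regulated together were not simulated. With no shift, 4% of lists of 30 fell outside, with a log2 shift of 0.25 it was 80%, and with 0.5 it was 100%. For lists of 12 the shares were 4%, 42% and 95%, and smaller lists were not simulated.

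The genes named follow a rule fixed before the data were examined. It takes the 10 largest rises and the 10 largest falls among called genes with at least 5 FPKM in the higher genotype, by the log2 ratio of (FPKM + 1). It adds Cnot3 and Trp53 always, and per list up to 4 members by size of change, called ones ahead of others. Loci without a name, loci with several symbols and genes at several loci are left out of that rule. A check of transcript length and GC content used GENCODE release M21 transcripts, with a lowess trend of span 0.3 removed from the log2 folds. Genes without a transcript under their deposited symbol were left out of it. It kept 90.2% of single-symbol genes, so list medians with the trend removed may rest on fewer members. Alternatives tried were pseudocounts of 0.1 and 5, other filters, median centring, rescaling to a common sum, unmatched random lists and other thresholds. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.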

Results

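RNA was sequenced from mouse bone marrow pro-B cells, the stage of B cell development at which the immunoglobulin heavy chain locus is rearranged. The cells were sorted as negative for other lineages, IgM and CD25, and positive for B220, CD43 and CD19. Control mice carried Cre at Mb1, the gene also called Cd79a, and deleted mice carried in addition floxed alleles of Cnot3, a subunit of the CCR4-NOT complex that shortens poly(A) tails of mRNAs. The series title asks how CNOT3 regulates early B cell development. Of 8 libraries, 2 formed an earlier set with 1 library per genotype and 6 formed a later set with 3 per genotype, and cells of 6 mice were pooled for each genotype. The values are the authors' FPKM, 1 per genotype, with the authors' confidence interval and q value. Read depth is unknown, and the precision is that of the intervals, whose median half-width among tested loci was 63.9% of the control FPKM. The p-values are those of the authors' Cuffdiff model, and which libraries they rest on is not stated. The spread between libraries may be technical.

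Cnot3 mRNA fell in the deleted pro-B cells. In the authors' deposited table, the Cnot3 locus (chromosome 7, 3596870 to 3629155, build not given in the sources used here) had 40.7 FPKM in control cells (interval 14.4 to 67.0). It had 14.0 FPKM in deleted cells (interval 0 to 32.4) in the authors' deposited table, a log2 fold change of −1.54 with q = 0.0299. Reads from exons outside the floxed part count toward this value, so it does not measure the efficiency of deletion. Of 15 measured CCR4-NOT subunits and adaptors, Cnot3 was the 1 that fell and none rose by the authors' q. Adjusted over the list alone, 1 rose and 1 fell, the rise being that of Btg1, an adaptor of the complex. Btg1 went from 44.2 to 75.4 FPKM in the authors' deposited table, with q = 0.0638 over all loci. The scaffold subunit Cnot1 had 79.1 FPKM in control and 59.0 in deleted cells in the authors' deposited table (q = 0.456). Of 23 other mRNA decay factors, such as poly(A)-binding and decapping proteins, none rose or fell over all genes or when adjusted over the list alone. The median log2 fold of (FPKM + 1) was −0.25 for the CCR4-NOT list, at percentile 2.74 of random lists of matched expression, and −0.24 for the other decay factors, at percentile 0.920. With a trend of length and GC content removed they were −0.10 (percentile 25.4) and −0.12 (percentile 11.2).

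Deletion of Cnot3 was accompanied by 199 changed loci among 9422 tested, 80 higher and 119 lower in deleted cells. They included a DNA repair enzyme, signalling inhibitors and a long noncoding RNA among the rises, and the B cell receptor inhibitor Cd22 among the falls. Of the 199, 177 were genes with 1 symbol at 1 locus (74 higher, 103 lower), 2 were genes whose symbol stands at several loci (Arl6ip1, lower, and Slc1a5, higher), 13 had no gene name and 7 had several symbols. The smallest change called was 1.68-fold, and 83 loci had the smallest p-value that the table reports, 5e-05. At an unadjusted p-value under 0.05 the count was 1249 loci, and at q under 0.01 it was 95. Among genes with a single symbol the median log2 fold was 0.00. Where a transcript length was known, the median was 5028 bases for genes called lower and 3431 for genes called higher. For all tested genes it was 3350 bases, and the calls were not adjusted for length.

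Among called genes listed with 1 symbol at 1 locus, the 10 largest rises were led by Ercc2. Larger called rises at loci outside that rule were those of the Snhg12 locus, 25.4-fold in the authors' deposited table, and of an unnamed locus on chromosome 15 listed at 0 in control cells. Ercc2, a DNA helicase of nucleotide excision repair and of the transcription factor TFIIH, went from 23.9 to 527 FPKM in the authors' deposited table, 22.0-fold. Its intervals were 0.178 to 47.7 FPKM in control and 497 to 557 in deleted cells in the authors' deposited table. The interval in deleted cells is narrow beside the median half-width of 63.9% in control cells, and the reason was not tested. Mgmt, which removes alkyl groups from guanine in DNA, rose 12.2-fold in the authors' deposited table, from 2.73 to 33.4 FPKM. Clgn, a chaperone of the endoplasmic reticulum, rose 7.63-fold and the tubulin gene Tubb2b 6.62-fold in the authors' deposited table. Tns1, which links integrins to actin, rose 7.71-fold from 1.19 to 9.16 FPKM in the authors' deposited table. Socs2, an inhibitor of cytokine signalling through STAT5, rose from 20.4 to 83.0 FPKM, and the noncoding RNA Neat1 of nuclear paraspeckles from 19.0 to 70.6 in the authors' deposited table. Myl10, Sh2d5 and 9030617O03Rik completed these 10, with 3.65-fold, 3.43-fold and 6.16-fold rises in the authors' deposited table.

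Among called genes listed with 1 symbol at 1 locus, the 10 largest falls were led by Rnf215 and Ddhd1, and several unnamed loci outside that rule fell as far as others of the 10. Rnf215 went from 162 to 5.11 FPKM and the phospholipase Ddhd1 from 231 to 8.05 FPKM in the authors' deposited table, 31.7-fold and 28.7-fold. Their control intervals, 141 to 184 and 199 to 263 FPKM in the authors' deposited table, were likewise narrow. Mmrn1 fell from 40.4 to 3.90 FPKM and the centriole gene Cep164 from 33.5 to 5.58 FPKM in the authors' deposited table. Cd22 fell from 16.1 to 2.45 FPKM in the authors' deposited table, 6.56-fold with q = 0.00568. Hipk3, a protein kinase gene, went from 100.2 to 20.5 FPKM in the authors' deposited table, and the interval in deleted cells reached 82.2. The membrane trafficking gene Ehd2 fell from 28.6 to 5.29 FPKM in the authors' deposited table. Tmem132e, 1700048O20Rik and Pcp4l1 were the other falls, at 6.91-fold, 5.21-fold and 5.19-fold in the authors' deposited table.

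**Figure D1:**
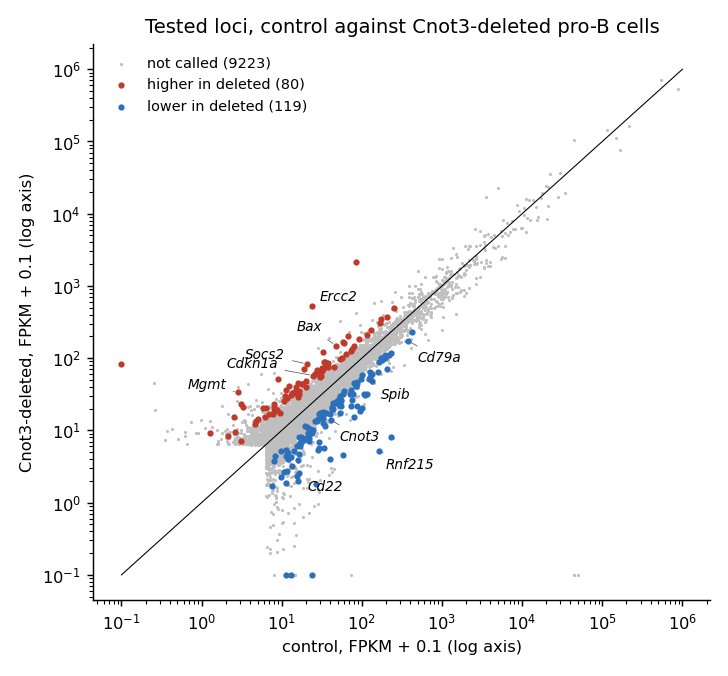
Authors' FPKM of the 9422 tested loci in control (horizontal) and Cnot3-deleted pro-B cells (vertical), each with 0.1 added, on log axes; each point is 1 locus and the line marks equal values. The 80 loci called higher lie above the line and the 119 called lower lie below it.

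The mRNAs of p53 target genes were higher in the deleted cells. Of 29 measured members of the list, 5 rose and none fell by the authors' q, and adjusted over the list alone 6 rose and 1 fell. The cell cycle inhibitor Cdkn1a rose from 24.6 to 57.3 FPKM and the pro-apoptotic gene Bax from 47.5 to 149.6 FPKM in the authors' deposited table, both with q = 0.00568. Ccng1 rose from 44.3 to 76.3 FPKM and Psrc1 from 11.3 to 35.6 FPKM in the authors' deposited table, and Mgmt, given above, was the other rise. Trp53 itself (chromosome 11, 69393860 to 69405375) had 141 FPKM in control (interval 73.5 to 208) and 205 in deleted cells (interval 111 to 299.6) in the authors' deposited table. That log2 difference of 0.54 in the authors' deposited table did not pass the test (p = 0.0237, q = 0.265). Across the list, 22 members were higher and 7 lower, and the median log2 fold of 0.48 lay at percentile 100 of matched random lists (0.29 with a pseudocount of 5). Mdm2, the ubiquitin ligase that p53 induces, had 35.9 FPKM in control and 24.1 in deleted cells in the authors' deposited table, which did not pass the test. Ccng1 and Mdm2 were named after their values were seen. The list was chosen knowing that p53 is a subject of this study, so it is not independent of it.

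Of 13 measured members of the BCL2 family, which controls mitochondrial apoptosis, Bax was the 1 that rose and none fell, also when adjusted over the list alone. Bbc3, which encodes the BH3-only protein PUMA, had 0.322 FPKM in control and 10.4 in deleted cells in the authors' deposited table, with q = 0.576. Bok, a relative of Bax, had 15.4 and 7.66 FPKM in the authors' deposited table, with q = 0.448. The family's median log2 fold was 0.05, at percentile 61.3, and turned to −0.094 with no filter, −0.030 at a mean FPKM of at least 5 and −0.037 without the length and GC trend.

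**Figure D2:**
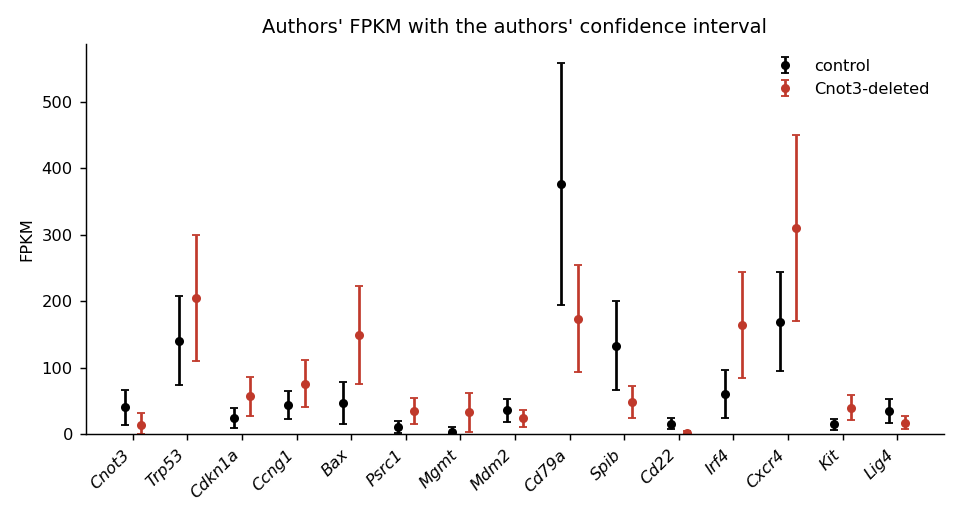
Authors' FPKM (vertical axis, starting at 0) of 15 genes in control (black) and Cnot3-deleted (red) pro-B cells; points are the authors' values per genotype and bars their confidence intervals. Bax went from 47.5 to 149.6 FPKM and Cd79a from 377 to 174, in the authors' deposited table, while Trp53 and Mdm2 did not pass the authors' test.

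Of 32 measured transcripts that define early B cells, 2 fell and 1 rose. The signalling chain gene Cd79a fell from 377 to 174 FPKM and the transcription factor Spib from 134 to 48.9 FPKM in the authors' deposited table. The transcription factor Irf4 rose from 60.4 to 164 FPKM in the authors' deposited table, and all 3 changes had q = 0.00568. Adjusted over the list alone, 1 rose and 3 fell, the added fall being Ikzf3, which had 23.7 and 11.3 FPKM in the authors' deposited table. The median log2 fold was −0.10, at percentile 38.0. Rescaling both genotypes to the same sum of FPKM moved the median of all single-symbol genes to 0.14 and this one to 0.08, at percentile 37.1. The B lineage regulators Pax5 (262 and 218 FPKM) and Ebf1 (304 and 207 FPKM) in the authors' deposited table had q = 0.870 and q = 0.511. Pax5 and Ebf1 were named after their values were seen.

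Genes of the step from pro-B to pre-B cells changed in both directions. Of 11 measured, Irf4 and the chemokine receptor Cxcr4 rose, and Cd22 and Arpp21 fell. Cxcr4 went from 169 to 311 FPKM and Arpp21 from 45.6 to 24.0 FPKM in the authors' deposited table. The counts were 3 rises and 4 falls adjusted over the list alone. The list's median log2 fold of −0.90 lay at percentile 0, with 8 members lower and 3 higher. It was −0.51 with a pseudocount of 5, −0.60 at a mean FPKM of at least 5 and −0.59 on rescaling to a common sum. Of 12 genes of mature B cells, Tnfrsf13c, the receptor for the survival factor BAFF, fell from 21.5 to 7.64 FPKM in the authors' deposited table and none rose. In this list 3 rose and 1 fell adjusted over the list alone. Ccr7 had 12.3 and 26.3 FPKM and Cxcr5 5.02 and 21.8 FPKM in the authors' deposited table, with q = 0.124 and q = 0.148. The mature B cell median was −0.38, at percentile 0.520, and −0.25 at percentile 4.89 in members with a mean FPKM of at least 5. Of 6 plasma cell genes, Irf4 and Xbp1 rose and none fell, also when adjusted over the list alone. Xbp1, a transcription factor of secretory cells, went from 34.7 to 87.2 FPKM in the authors' deposited table. The plasma cell median was 0.75, at percentile 100, and 0.19 at percentile 87.4 with no filter. With the trend of length and GC content removed it was 1.29, at percentile 100. Members without a transcript length are left out there, so the higher median need not come from removing the trend.

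Of 25 measured genes of V(D)J recombination and of heavy chain locus regulation, 1 fell. Lig4, the ligase that joins the broken ends, fell from 34.9 to 17.4 FPKM in the authors' deposited table (q = 0.0275). None rose, and the counts were the same when adjusted over the list alone. The recombinase genes Rag1 (315 and 282 FPKM) and Rag2 (91.4 and 83.8 FPKM) and the polymerase gene Dntt (754 and 858 FPKM) did not pass the test in the authors' deposited table. The DNA end-binding gene Xrcc6 had 175 and 262 FPKM in the authors' deposited table, with q = 0.202. The median log2 fold was −0.05, at percentile 50.5, and on the same rescaling it was 0.12, at percentile 47.7. It was 0.050 without the length and GC trend, at percentile 91.2. Rag1, Rag2 and Dntt were named after their values were seen.

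The listed FPKM of loci from the variable part of the heavy chain locus was mostly lower in the deleted cells. The table names no variable segment, so this part was taken, after seeing that, as the unnamed loci between Adam6a and Zfp386 on chromosome 12 (114784625 to 117285934). In the GRCm38 RefSeq annotation all 183 heavy chain variable segments lie between these genes. Of 71 measured loci, 68 were lower and 3 higher, with a median of 9.0 FPKM in control and 1.13 FPKM in deleted cells. Their median log2 fold was −2.16 (quartiles −2.84 and −1.14), or 4.48-fold, at percentile 0 of random lists of unnamed loci elsewhere. The median was −3.32 with a pseudocount of 0.1 and −0.96 with a pseudocount of 5, both also at percentile 0. The central 95% of those lists ran from −0.40 to −0.01. Of 30 loci that the authors tested, 1 fell and none rose, and 4 had an unadjusted p-value under 0.05. Over all 9422 tested loci, 199 were called and 1249 had an unadjusted p-value under 0.05, which are similar shares. The authors' test of single loci thus showed no clear excess of changes in this region. The locus of the region that fell, at 115984502 to 115984791, had 23.7 FPKM in control and was listed at 0 in deleted cells in the authors' deposited table (q = 0.0250). Of the 71 measured loci, 17 were listed at 0 in deleted cells and none in control cells. Several of the 71 share 1 deposited range, so they are not 71 separate positions. Summed within ranges, all 42 ranges were lower in deleted cells.

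Along the variable part, loci were lower in each of 3 stretches of equal length. The medians from the Adam6a end were −2.20 (24 of 24 lower), −2.36 (23 of 24) and −1.29 (21 of 23). Loci that share 1 deposited range were placed at the same midpoint, so each count includes loci that are not separate positions. In the stretch farthest from Adam6a, many loci share the range 116500894 to 116805763, and its difference from the other stretches was not tested. The side of the locus with the constant, joining and diversity segments, between Tmem121 and Adam6b, had 9 loci lower and 7 higher of 16. The median log2 fold there was −0.19, at percentile 45.2. Its most abundant locus, at 114655810 to 114667982, had 726 FPKM in control and 570.2 in deleted cells in the authors' deposited table, with q = 0.832. Reads shared between near-identical segments make the value of any single variable locus uncertain.

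**Figure D3:**
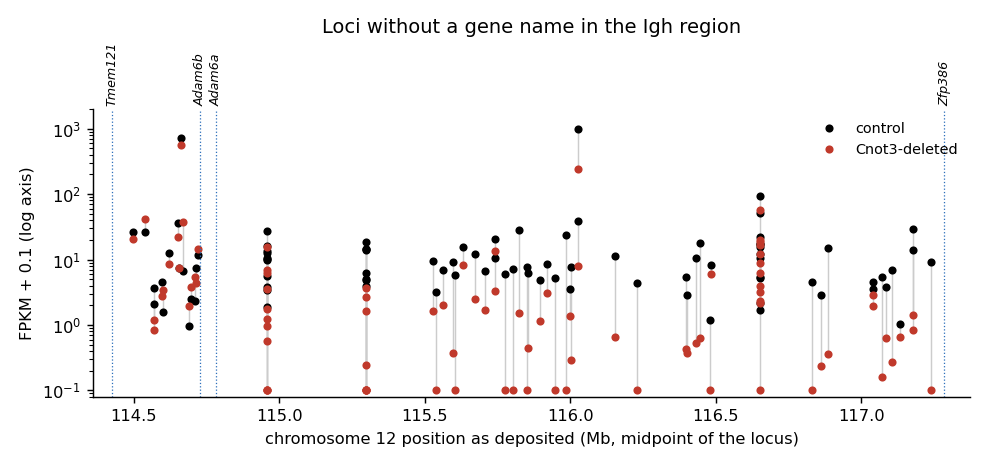
Authors' FPKM plus 0.1 (log axis) of unnamed loci on both sides of the heavy chain locus against position on chromosome 12 in Mb, as deposited, in control (black) and Cnot3-deleted (red) pro-B cells; grey lines join the values of 1 locus and dotted lines mark flanking genes. Between Adam6a and Zfp386, 68 of 71 measured loci were lower in deleted cells, and 17 of the 71 were listed at 0 there.

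Of 30 S phase genes, Cdt1, Mcm3 and Mcm6, which load and form the replicative helicase, rose and none fell, with 20 members higher and 10 lower. Cdt1 went from 33.9 to 89.1 FPKM, Mcm3 from 128 to 244 and Mcm6 from 205 to 367 in the authors' deposited table. Of the S phase genes, 6 rose and 1 fell adjusted over the list alone, and the median of 0.32 lay at percentile 100 (0.20 without the length and GC trend). Of 29 genes of G2 and M phase, the kinetochore gene Cenpf fell from 48.7 to 25.7 FPKM in the authors' deposited table and none rose, also when adjusted over the list alone. Birc5 had 220.4 and 141 FPKM and Kif23 90.7 and 55.0 FPKM in the authors' deposited table, with q = 0.191 and q = 0.117. The median of the G2 and M list was −0.26, at percentile 0.480, with 20 members lower and 9 higher. With a trend of length and GC content removed it was −0.22, at percentile 2.94 and inside the random range. Of 13 cyclins and inhibitors of G1, Ccnd2 rose from 31.2 to 55.7 FPKM in the authors' deposited table, Cdkn1a rose too, and none fell. With q adjusted over the list alone, 2 rose and 1 fell, and the median of 0.14 lay at percentile 91.1. Of 28 measured histone genes, 6 were tested, and none rose or fell over all genes or when adjusted over the list alone. Their median was −0.94, at percentile 0, with 19 lower and 9 higher. It was −0.26 with no filter and −0.36 with a pseudocount of 5, and was also at percentile 0 in both. Hist1h4d had 3.0 FPKM in control and was listed at 0 in deleted cells in the authors' deposited table. Most of the 28 had a few FPKM or less in both genotypes, and how fully these libraries capture histone mRNAs was not tested.

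Stress and metabolic genes changed in few members, all upward. Of 18 genes of the integrated stress and unfolded protein responses, Phgdh of serine synthesis rose from 62.8 to 115 FPKM in the authors' deposited table, Xbp1 rose as given above, and none fell. The stress list had 5 rises and no fall adjusted over the list alone, and the median of 0.26 lay at percentile 98.8, but at 0.093 and percentile 90.7 with no filter. Of 17 glycolysis genes, the phosphofructokinase Pfkp rose from 10.98 to 30.2 FPKM in the authors' deposited table and none fell. Of the glycolysis genes, 2 rose and none fell adjusted over the list alone, and the median of 0.11 lay at percentile 88.1. It was 0.033 at a mean FPKM of at least 5 and 0.048 without the length and GC trend. None of 19 genes of cholesterol and lipid synthesis, 22 immediate early or AU-rich element mRNAs and 14 interferon-stimulated genes rose or fell by the authors' q. Of these, 1 of the immediate early and AU-rich element mRNAs fell adjusted over the list alone. It was Zfp36l1, which had 55.7 and 32.9 FPKM in the authors' deposited table (q = 0.0824). The medians were 0.18 (percentile 89.9), −0.24 (percentile 1.33, but −0.096 at percentile 8.70 with no filter) and −0.20 (percentile 7.95). The interferon median lay outside, at −0.29 and percentile 1.4, without the length and GC trend. None of 80 ribosomal protein genes changed, also when adjusted over the list alone, and their median of 0.07 lay at percentile 100.

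Genes on the lists of other blood lineages moved in different directions. Not all of them are confined to cells that the sort was meant to exclude, so a change need not mean admixed cells. Of 8 stem and multipotent progenitor genes, the receptor Kit rose from 15.1 to 39.9 FPKM in the authors' deposited table and none fell. Of 9 myeloid genes, Mpo, the granule enzyme of neutrophil precursors, fell from 13.4 to 3.09 FPKM in the authors' deposited table and none rose. The carbonic anhydrase Car2, on the erythroid and megakaryocyte list, rose from 67.3 to 201 FPKM in the authors' deposited table. Of 6 plasmacytoid dendritic cell genes, the transcription factor Tcf4, which B cells also express, fell from 43.9 to 23.6 FPKM in the authors' deposited table. None of 3 T and NK cell genes, 5 sex-specific genes and 14 reference genes changed, also when adjusted over the list alone. Adjusted over the list alone, 1 rose and 1 fell among the stem and progenitor genes, 2 fell among the myeloid and 2 among the plasmacytoid genes. The erythroid list kept its single rise when adjusted over the list alone. The medians were 0.10 for progenitors (percentile 65.9), −0.72 for myeloid (percentile 0.0600, but 0.64 in members with a mean FPKM of at least 5) and 0.55 for erythroid genes (percentile 94.1). The erythroid median was −0.17 with no filter and 1.57 in members with a mean FPKM of at least 5, where it lay outside at percentile 99.6. They were 0.18 for plasmacytoid (percentile 76.5), 0.48 for T and NK (percentile 93.7), −0.31 for sex-specific (percentile 7.93) and −0.27 for reference genes (percentile 3.54). In members with a mean FPKM of at least 5 the plasmacytoid median was −0.87, outside at percentile 0.120, and with no filter the T and NK median was −0.01. The sex-specific median was 0.034 without the length and GC trend, and the reference median lay outside, at percentile 1.98, against unmatched random lists. The reference gene B2m had 3055 and 2117 FPKM and Ywhaz 300.1 and 217 FPKM in the authors' deposited table, with q = 0.437 and q = 0.440.

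Of the 26 lists, 12 had a median outside the central 95% of matched random lists, 5 of them higher and 7 lower, where 1.3 would be outside by chance. Of the 12, the decay factor, mature B, plasma cell, myeloid, G2 and M, immediate early, stress and ribosomal medians came inside that range under at least 1 other filter, matching or correction. The percentile describes these pooled values: genes are not replicates, and random lists ignore that genes of a list are regulated together.

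**Figure D4:**
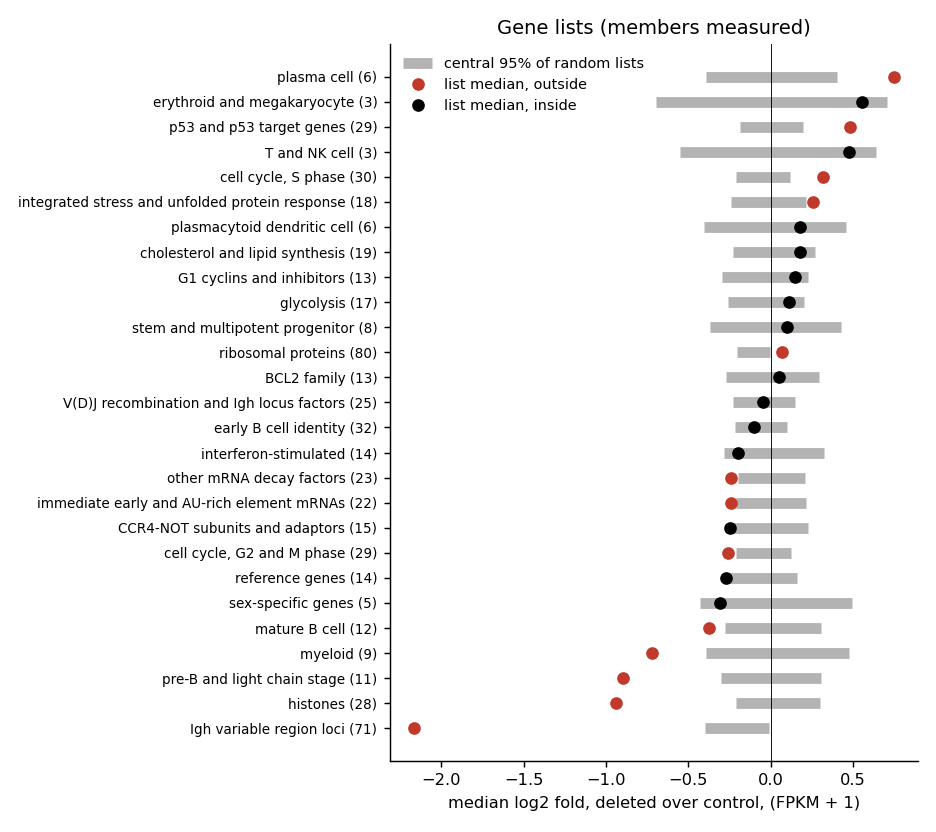
Median log2 fold of (FPKM + 1), deleted over control, of each gene list and of the variable heavy chain loci, with the number of measured members in brackets; grey bars span the central 95% of 10000 random lists of matched expression, drawn from unnamed loci for the variable part and from genes with 1 symbol for the others. The plasma cell (0.75), p53 (0.48) and S phase (0.32) medians lie above their bars, and the variable loci (−2.16), histones (−0.94) and pre-B genes (−0.90) below.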

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

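The count of loci with 1 symbol, the removal of the length and GC trend and the value per deposited range were chosen after seeing the data. No paired analysis was possible because the table holds 1 pooled value per genotype. For the same reason, leaving out libraries, a term for the set, and set tests over libraries were not run, and pseudocounts and rescaling do not touch the authors' calls.

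At q under 0.01 the count of changed loci was 95 (37 higher, 58 lower) against 199, a stricter threshold on the same values. It was 199 with a 1.5-fold minimum. With q recomputed over the loci kept, it was 198 at a mean FPKM of at least 5. Recomputed likewise among genes with 1 symbol at 1 locus, it was 178, where the authors' q gave 177. Rescaling to a common sum moved the median of all single-symbol genes to 0.14. The log2 change of Cnot3 ran from −1.53 to −1.18 and that of Trp53 from 0.53 to 0.72. The p53 list median ran from 0.29 (pseudocount 5) to 0.50 and stayed outside the random lists. The variable heavy chain median ran from −3.32 (pseudocount 0.1) to −0.96 (pseudocount 5), and was −2.31 per deposited range, also outside in each.

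The number of lists outside was 12, and 8 without a filter, 10 at a mean FPKM of at least 5 and 9 without the length and GC trend. Medians that changed sign at a mean FPKM of at least 5 were the myeloid (0.64), plasmacytoid (−0.87) and BCL2 (−0.030) ones, and with no filter the BCL2 (−0.094), T and NK (−0.012) and erythroid (−0.17) ones. Filters change which members are counted. On rescaling to a common sum, the early B (0.080) and V(D)J (0.12) medians changed sign, as the shift of all genes by 0.14 makes medians near 0 do, while their percentiles stayed at 37.1 and 47.7. With the length and GC trend removed, the BCL2 (−0.037), V(D)J (0.050), sex-specific (0.034) and ribosomal (−0.050) medians did. The cause of the last 4 was not tested. Apart from these 12 values and those of the p53 list, 174 list values kept their direction and side of the threshold. With their direction kept, 11 came inside and 3 went outside. The values that went outside were those of the erythroid list at a mean FPKM of at least 5, the interferon list without the trend and the reference list against unmatched lists, and the plasmacytoid value above also lay outside. The lists that came inside in some setting were the decay factor, mature B, plasma cell, myeloid, G2 and M, immediate early, stress and ribosomal lists. Read depth is not given, so how far it limits low genes is unknown.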

Other observations

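The genes and regions in this paragraph and the next were picked after their values were seen, and the genes of this paragraph were not tested as a group. Cish, like Socs2 an inhibitor of cytokine signalling, rose from 6.25 to 20.2 FPKM and the kinase gene Pim1 from 72.2 to 126 FPKM in the authors' deposited table, with q = 0.0349 and q = 0.0453. The receptor gene Il7r itself had 141 and 148 FPKM in the authors' deposited table (q = 0.962). Of transcription factors of early lymphoid cells, Hhex fell from 72.2 to 21.5 FPKM and Bcl11a from 84.9 to 41.0 FPKM in the authors' deposited table. The phosphatase gene Pten fell from 99.8 to 58.9 FPKM, and the kinase gene Sgk1 from 74.6 to 26.0 FPKM in the authors' deposited table. Laptm5, a lysosomal protein gene of blood cells, fell from 230.5 to 119 FPKM, and Plac8 rose from 249 to 502 FPKM in the authors' deposited table.

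Several called loci carried more than 1 symbol and cannot be assigned to a single gene. The locus of Snhg12 with the small nucleolar RNAs Snora44, Snora61 and Snord99 went from 84.2 to 2138 FPKM in the authors' deposited table. The interferon-inducible GTPase loci moved apart: Gbp3 with Gbp7 rose from 26.2 to 59.6 FPKM, and Gbp4 with Gbp9 and Gbp11 fell from 28.8 to 6.80 FPKM in the authors' deposited table. The locus of Serpina3f, Serpina3g and Serpina3n rose from 8.75 to 51.5 FPKM in the authors' deposited table. The unnamed loci of the kappa light chain region, between Tacstd2 and Rpia on chromosome 6, were lower in 22 of 28 cases, with a median log2 fold of −0.89 at percentile 0.0200. Of these loci the authors tested 8, and none of the 8 was called.

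All tests of explanations in the paragraphs that follow were chosen after the results were seen. The lower FPKM across the variable heavy chain loci was set against a general fall of weakly expressed unnamed loci. The lowest median of the 10000 matched random lists of such loci was −0.55, against −2.16 in the region. This repeats the placement of the region among the same lists given above, so it is not a separate test. It shows only that lists of unnamed loci elsewhere, of similar mean expression, did not fall as far. The lists were not matched on locus length or on shared ranges, so a fall tied to these was not tested. Reassignment of shared reads among segments of the region would raise some loci as others fall. Of 71 measured loci 68 were lower and 3 higher, and all 42 ranges were lower when summed. The deposited spans of loci of at least 150 bp ran from 289 to 326873 bp, and read counts are not given. Reads gained by the higher loci therefore cannot be weighed against those lost, and these counts do not decide it. The value of any single locus stays uncertain. Over loci of at least 150 bp the summed FPKM was 3.29 times as high in control cells. FPKM is divided by length, so this sum does not decide between reassignment and a fall of the region either. Fewer cells of later stages among the sorted cells cannot be told apart from less transcription or rearrangement per cell. The pre-B list had a median of −0.90 but members that rose, Irf4 and Cxcr4, and the CD25-negative gate would remove pre-B cells that carry CD25. Fewer later cells could also lower the unnamed kappa light chain loci. Of those, 22 of 28 were lower, with a median of −0.89, though none of the 8 tested was called. An effect of losing Cnot3 itself was not tested apart from these.

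The higher p53 target levels were set against a trend with transcript length and GC content, since log2 folds correlated with both across 7233 tested genes (Spearman's rho −0.23 and 0.23, genes not being independent replicates). With that trend removed the list median was 0.40, still outside the random lists, with 28 of 29 members having a length. A scaling error between the genotypes would move all genes alike, but the list median exceeded that of all single-symbol genes by 0.47. No test here bears on p53 activity itself, and an effect of losing Cnot3 stays open as untested. The Mdm2 level, 35.9 FPKM in control and 24.1 in deleted cells in the authors' deposited table, lay in the opposite direction without passing the test.

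The fall of Cd79a was set against a general fall of early B cell transcripts. That list's median was −0.10 (quartiles −0.39 and 0.04), against the log2 fold of −1.11 for Cd79a, so most members did not fall as far. Cd79a was picked as a called fall of this same list, so its distance from the median does not decide the question. Of the members 22 were lower and 10 higher, and a smaller general fall stays open. Cre replaces part of 1 copy of Cd79a in these mice, and the deleted cells had 0.462 of the control level. The labels give the Cre allele for both genotypes, while the table heads its control column WT. A difference in the Cre allele therefore cannot be told apart from an effect of losing Cnot3, because the table names no library, and it may also bear on other genes changed here. Cd79a and Cnot3 both lie on chromosome 7, as do Ercc2, Ehd2, Cd22, Spib, Bax, Mgmt and the called loci of Slc1a5 and Arl6ip1. Cnot3 starts at 3596870, and Ehd2, Slc1a5, Ercc2, Cd79a and Cd22 start between 16532337 and 31650422. Spib, Bax, Arl6ip1 and Mgmt lie farther away. Most other named changes lie on other chromosomes, and the share of all called loci on chromosome 7 was not counted. By the labels, the deleted mice alone carried floxed Cnot3 alleles. Whether DNA linked to those alleles bears on the genes of chromosome 7 was not tested.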
